A study of Mus musculus with 13 samples.

How the data were processed

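RNA levels were measured in 13 mouse cell samples, each on 1 one-colour Agilent array with Cy3-labelled RNA per the labels. The deposited values are intensities on a linear scale, read from the series' value table. Per the submitters' processing notes they came from Agilent Feature Extraction 10.5.1.1, while the background handling and any later step are not given in the sources used here. All values lay above 0 and the array medians and 75th percentiles differed, so no scaling to a common median, percentile or distribution was seen, while other scaling cannot be excluded. Batch, slide and scan date were not given in the sources used here.

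The table holds 45018 features. The platform's probe table gave 1 gene symbol for 33653 of them, several for 56 and none for 11309, and no gene was named from a feature with several symbols. Of the named features, 33517 matched the mouse gene table by gene ID and 0 were renamed. Log2 intensities were shifted by each array's 75th percentile and averaged over the probes of a gene, which gave 19087 genes, of which 8343 had several probes. No named gene had probes called in opposite directions. The planned design kept the deposited normalization if one had been made and otherwise set this shift.

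The local floor of an array was the lowest value in a window of 101 features along the table, and a feature counted as measured above 3 times that floor. A gene was not above the limit on an array only if none of its probes was. Where this held on every array of the dimmer group, the fold is a lower bound, the bright group's mean against the mean over the dim arrays of the higher of the limit and the gene's own level. No fold is given where both groups lay under the limit.

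TTF (3 arrays), iHep (4) and hepatocyte (4) were compared in 1 model with 1 mean per group in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit, eBayes), with Benjamini-Hochberg adjustment over all genes. A call needs an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Tables were handled in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6. MEF and the mixed culture, with 1 array each, stayed out of the model. For these, genes were counted at an absolute log2 difference of at least 2 from the TTF mean and outside the TTF range, and a list's median was ranked among 10000 random lists matched on mean level. Positions between TTF and hepatocyte were projections over all genes. Calls shared between the comparisons with TTF were set against 100 simulations of unchanged groups.

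The 28 gene lists were fixed before the data were examined and tested with camera at its preset correlation of 0.01, adjusted over lists and comparisons, and again with an estimated correlation. With the estimate, 2 of the 51 called list results held, both of the posterior Hox list. Lists under 5 measured genes had no camera test. The lists cover plasma carrier proteins and apolipoproteins, coagulation and complement, acute phase, liver transcription factors, factors transduced in the published protocol (from general knowledge, since the labels name none), cytochrome P450 and drug metabolism, bile acid synthesis and transport, urea cycle and amino acid metabolism, glucose and glycogen metabolism, sterol and fatty acid synthesis, fatty acid oxidation and ketogenesis, fetal liver and progenitor, biliary epithelium, and epithelial junctions and keratins. They also cover extracellular matrix, mesenchymal transcription factors and markers, posterior Hox, anterior Hox, proliferation, p53 targets and Ink4/Arf locus, interferon response, intestinal epithelium, stomach, lung and pancreas epithelium, macrophage and leukocyte, endothelium, hepatic stellate cell, keratinocyte, cartilage and muscle, and pluripotency.

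Named genes followed a rule also fixed before the data were examined. It took the 5 called genes with the largest increase and the 5 with the largest decrease whose groups did not overlap on any array and whose symbol was not a provisional one. From each list it took the 2 called members with the largest increase and the 2 with the largest decrease, or the 2 with the largest change where none was called. A fixed set of liver, epithelial and fibroblast markers was added in each comparison, of which the measured ones were Alb, Ttr, Trf, Afp, Hnf4a, Cyp7a1, Cyp3a11, Cdh1, Krt18, Krt19, Col1a1, Vim, Cdkn2a, Gata4 and Foxa3. For the single arrays the rule took the 5 largest increases and decreases among counted genes and the same markers. Genes outside the rule are named as chosen after their values were seen.

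The fit was tested on simulated data for the comparison of iHep with TTF, with 200 of 19087 genes changed. It recovered 16% of genes changed by 1.5 log2 units, 48% at 2, 82% at 3 and 86% at 4, with 8 false calls among unchanged genes and 0 calls in the simulated comparison of hepatocytes with TTF, where nothing was changed. The array count therefore limits what smaller changes can show. The alternatives set beforehand were quantile normalization, equal medians, leaving out the lowest 25% of genes, the brightest probe or each probe on its own, only the groups compared, a replicate block, eBayes with trend and robust, adjusted p alone, and leaving out each replicate. A common floor at -7, leaving out pairs of iHep or hepatocyte arrays, and a block of array sets were added after seeing the data. Genome coordinates were not used here.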

Results

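Gene expression was measured on 13 one-colour microarrays of mouse cells, all p19Arf-null and of a mixed C57BL/6-129 background. The groups were tail-tip fibroblasts (TTF, 3 arrays), induced hepatocyte-like cells (iHep, 4 arrays, each from a single epithelial colony) and cultured primary hepatocytes (4 arrays). A culture of transduced fibroblasts sampled before colonies were picked and a culture of mouse embryonic fibroblasts (MEF) had 1 array each, so neither had a replicate. The iHep cells came from tail-tip fibroblasts given lentiviruses for 3 liver-enriched transcription factors. TTF and MEF were sampled at day 42 in serum-containing DMEM, whereas iHep, hepatocyte and mixed cultures were sampled at day 21, with iHep and hepatocytes in a modified Block's medium. Day and medium therefore went with the group when iHep or hepatocytes were compared with TTF. The 75th percentile of intensity ranged from 1140 on hepatocyte replicate 1 to 2260 on hepatocyte replicate 4, and between 63.2% (iHep replicate 2) and 83% (iHep replicate 3) of features lay above the limit of measurement. The number of arrays limits the precision. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure the spread between these arrays, which may be technical.

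Fold changes are log2 values with the standard error (SE) of the limma fit over 4 iHep, 3 TTF and 4 hepatocyte arrays, and levels are log2 intensity relative to the array's 75th percentile. A gene was called higher or lower at an adjusted p under 0.05 and a change of at least 2-fold. Where no array of the dimmer group rose above the limit of measurement, the difference is given as "at least N-fold". The gene targeted in these mice, Cdkn2a, encodes both p19Arf and p16Ink4a. Its level was 1.88 ± 0.38 (SD, n = 3) in TTF, 1.63 on the MEF array and 1.55 on the mixed-culture array. It lay between -1.16 and 0.71 on the iHep arrays and between -3.69 and -0.78 on the hepatocyte arrays. The position of its probes relative to the deleted part was not analysed here, so this level does not check the genotype.

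The comparison of iHep with TTF asks how the induced colonies differed from tail-tip fibroblast cultures. These need not be the source of each colony, as Xist and a Y-linked gene set 2 of the 4 iHep arrays apart from all TTF arrays. The lists of liver secretory, epithelial junction and intestinal genes were called higher and those of matrix and mesenchymal genes lower at the preset correlation, through part of their members. None of these calls was kept with an estimated correlation. Alb, which encodes serum albumin, rose by 9.01 ± 0.79 (SE, n = 4 and 3, adjusted p = 5.7e-05), with 2 of 3 TTF arrays above the limit. Afp, the fetal liver counterpart of albumin, rose by 11.53 ± 1.05 (adjusted p = 6.9e-05). Cdh1, which encodes the epithelial adhesion protein E-cadherin, rose by 10.07 ± 0.58 (adjusted p = 3e-06). Among the largest increases was that of Reg3g, a secreted antimicrobial lectin of the gut, at 15.54 ± 0.73 with 1 of 3 TTF arrays above the limit. Mfap5, a microfibril gene, was among the largest decreases and fell by 11.03 ± 1.17, a value that depends on the limit, since only 1 of 4 iHep arrays lay above it. In all, 1309 genes were higher and 1244 lower in iHep among 19087 tested.

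Among plasma carrier proteins and apolipoproteins, 16 of 25 measured genes rose and 9 were not called, with 17 higher when adjusted over the list alone (camera adjusted p = 9.9e-13, adjusted p = 0.11 with an estimated correlation). Ahsg, which encodes fetuin-A, was at least 5279-fold higher and the copper carrier gene Cp rose by 10.65 ± 0.57. Ttr and Trf, for the carriers of thyroxine and iron, rose by 7.52 ± 1.27 (1 of 3 TTF arrays above the limit) and 7.7 ± 1.49. Ahsg and Trf lay lowest on iHep replicate 2 (levels of -0.49 and 1.25, against 3.84 to 8.29 and 5.35 to 8.28 on the others). Their values therefore depend on that array. Of 30 coagulation and complement genes 10 rose, 1 fell and 19 were not called (10 and 2 adjusted over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.29 with an estimated correlation). The fibrinogen chain gene Fgb rose by 12.52 ± 0.68 and its partner Fgg was at least 1084-fold higher. In the acute phase list 6 of 18 rose and 12 were not called (7 adjusted over the list alone, camera adjusted p = 2.6e-07, adjusted p = 0.14 with an estimated correlation), with Lcn2, an iron-sequestering lipocalin gene, up by 13.1 ± 0.88 (2 of 3 TTF arrays above the limit) and Saa3, a serum amyloid gene, by 10.24 ± 0.65.

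Liver transcription factors had 6 of 22 members higher, 1 lower and 15 not called (7 and 2 adjusted over the list alone, camera adjusted p = 0.0073, adjusted p = 0.34 with an estimated correlation). Foxa2, a pioneer factor of endoderm, rose by 7.96 ± 0.34 with 1 of 3 TTF arrays above the limit, while Tbx3, a T-box repressor, fell by 3.29 ± 0.43. Hnf4a, a nuclear receptor central to the hepatocyte programme, rose by 4.95 ± 0.61 (adjusted p = 0.00043). Of the factors of the published protocol, Foxa3 was at least 12.1-fold higher and Gata4 was not called at 1.57 ± 0.79 (adjusted p = 0.24). For these factors 1 of 2 measured genes was higher, also when adjusted over the list alone, and probes need not detect the introduced copies. Gata4 lay at -7.03 and -7.23 on iHep replicates 1 and 2, within the TTF range of -8.01 to -6.78, and at -4.04 and -4.27 on replicates 3 and 4.

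In the cytochrome P450 and drug metabolism list 13 of 43 genes rose, 1 fell and 29 were not called (16 and 2 adjusted over the list alone, camera adjusted p = 3.3e-05, adjusted p = 0.22 with an estimated correlation). The glutathione transferase gene Gsta3 rose by 8.43 ± 0.73 and the epoxide hydrolase gene Ephx2 by 8.06 ± 0.6, but Cyp4v3 fell by 4.31 ± 0.42 and Cyp3a11 was not called (0.99 ± 0.62), although it was without TTF replicate 1 (1.88, adjusted p = 0.018). Bile acid synthesis and transport had 6 of 26 higher, 1 lower and 19 not called (7 and 1 adjusted over the list alone, camera adjusted p = 0.0048, adjusted p = 0.34 with an estimated correlation). The peroxisomal oxidase gene Acox2 rose by 7.56 ± 0.78 and Cyp7b1 fell by 7.11 ± 1.26 (2 of 4 iHep arrays above the limit), whereas Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was not called (0.39 ± 0.33). For urea cycle and amino acid metabolism 2 of 26 rose, 2 fell and 22 were not called, the same numbers as adjusted over the list alone, and the list was not called (camera adjusted p = 0.51). Its member Ass1, for argininosuccinate synthase, fell by 4.98 ± 0.87. Glucose and glycogen metabolism had 4 of 15 higher and 11 not called (5 higher and 1 lower adjusted over the list alone), among them the coactivator gene Ppargc1a at 3.69 ± 0.67. Its camera adjusted p of 0.016 became adjusted p = 0.31 with an estimated correlation and 0.093 without iHep replicate 4. In sterol and fatty acid synthesis 4 of 24 rose and 20 were not called (5 adjusted over the list alone, camera adjusted p = 0.0067, adjusted p = 0.41 with an estimated correlation). In fatty acid oxidation and ketogenesis 4 of 21 rose and 17 were not called (4 adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.29 with an estimated correlation).

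Epithelial junction and keratin genes rose in 24 of 40 cases, with 16 not called (26 higher adjusted over the list alone, camera adjusted p = 1.4e-19, adjusted p = 0.061 with an estimated correlation). Besides Cdh1, the claudin gene Cldn2 rose by 10.59 ± 0.57, with 1 of 3 TTF arrays above the limit, and the tricellular junction gene Lsr by 10.32 ± 0.59. Biliary markers rose in 3 of 17 cases and 14 were not called (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.31 with an estimated correlation), with Krt23 at least 2545-fold higher, the chloride channel gene Cftr up by 5.81 ± 0.65 and Krt19 up by 4.02 ± 0.61. In the fetal liver and progenitor list 5 of 16 rose, 3 fell and 8 were not called (7 and 4 adjusted over the list alone, camera adjusted p = 0.2, but 8.4e-07 with each probe on its own). Peg3 rose by 7.47 ± 0.82 with 2 of 3 TTF arrays above the limit, whereas the imprinted genes Dlk1 and Meg3 fell by 7.86 ± 0.53 and fell by 6.3 ± 1.07, each with 3 of 4 iHep arrays above the limit.

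Extracellular matrix genes fell in 30 of 40 cases and 10 were not called (35 lower adjusted over the list alone, camera adjusted p = 1.6e-19, adjusted p = 0.13 with an estimated correlation). Col5a2 fell by 9.62 ± 1.86, with 3 of 4 iHep arrays above the limit. It lay at -6.71 and -7.43 on iHep replicates 1 and 2 against -0.6 and 0.09 on replicates 3 and 4. Lox, which cross-links collagen, fell by 9.22 ± 1.31, and, outside the lists, the integrin-like gene Itgbl1 was at least 756-fold lower. Mesenchymal transcription factors and markers had 24 of 37 lower, 1 higher and 12 not called (27 and 2 adjusted over the list alone, camera adjusted p = 5.2e-13, adjusted p = 0.12 with an estimated correlation). The exception was Nt5e, for the surface nucleotidase CD73, which rose by 5.42 ± 0.33. Col1a1, the main fibrillar collagen gene, fell by 7.99 ± 2.3 (adjusted p = 0.042), with levels of -6.06 and -3.72 on iHep replicates 1 and 2 against 3.1 and 3.98 on replicates 3 and 4. Its call ended without TTF replicate 1 (adjusted p = 0.1), 2 (0.12) or 3 (0.12), without iHep replicate 1 (0.07) or 2 (0.088), and without hepatocyte replicate 1 (0.056) or 4 (0.054), as it did with each probe on its own (0.056) and with only the groups compared (0.079). In these settings the fold change lay between -8.19 and -6.2. Of the alternatives chosen after seeing the data, the call ended with the common floor (-7.98, adjusted p = 0.072) and without iHep replicates 1 and 2 (-3.78, adjusted p = 0.11).

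Posterior Hox genes, which mark the tail and hind trunk, were mostly not called between iHep and TTF. Of 17 measured, 2 were lower and 15 not called, the same as adjusted over the list alone, and the list was not called (camera adjusted p = 0.44). Hoxc13 fell by 3.88 ± 0.5, with 2 of 4 iHep arrays above the limit. Anterior Hox genes had 1 of 20 higher and 19 not called (1 adjusted over the list alone, camera adjusted p = 0.15). Proliferation genes had 1 of 39 lower and 38 not called (0 adjusted over the list alone). Camera gave this list an adjusted p of 0.015, which was adjusted p = 0.73 with an estimated correlation, 0.3 without TTF replicate 2, 0.15 without iHep replicate 3 and 0.059 without iHep replicate 4. Of the p53 targets and the Ink4/Arf locus, 3 of 18 were higher and 15 not called (3 higher and 2 lower adjusted over the list alone), the median lay below 0, the mean above 0 and the test pointed down (camera adjusted p = 0.99). Perp, an apoptosis-linked gene also needed for desmosomes, rose by 6.72 ± 1.34 with 2 of 3 TTF arrays above the limit. Interferon response genes had 4 of 23 lower and 19 not called (4 adjusted over the list alone), among them Ifit1, which fell by 3.39 ± 0.43. The camera adjusted p of 0.022 was adjusted p = 0.54 with an estimated correlation, 0.054 without TTF replicate 1 and 0.075 without iHep replicate 2.

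Markers of other cell types were measured beside these groups. Intestinal epithelium genes rose in 9 of 23 cases and 14 were not called (10 adjusted over the list alone, camera adjusted p = 5.3e-08, adjusted p = 0.061 with an estimated correlation), including Vil1, for the brush border protein villin, at 9.59 ± 0.93. In the stomach, lung and pancreas list 5 of 23 rose and 18 were not called (5 adjusted over the list alone, camera adjusted p = 0.0083, adjusted p = 0.3 with an estimated correlation). Gkn2, a gastric mucosal gene, rose by 12.23 ± 2.31 with 2 of 3 TTF arrays above the limit. This value too depends on iHep replicate 2, at -3.34 against 5.8 to 8.33 on the others. The surfactant protein gene Sftpd rose by 10.12 ± 0.93, with 1 of 3 TTF arrays above the limit. Macrophage and leukocyte genes had 3 of 24 higher and 21 not called (3 adjusted over the list alone, camera adjusted p = 0.24, but 0.0026 with each probe on its own), and endothelial genes 4 of 22 higher, 1 lower and 17 not called (4 and 1 adjusted over the list alone, camera adjusted p = 0.31). Hepatic stellate cell genes had 2 of 16 higher, 1 lower and 13 not called (2 and 1 adjusted over the list alone), with a median above 0, a mean below 0 and a test pointing down (camera adjusted p = 0.96). The keratinocyte, cartilage and muscle list had 1 of 24 higher, 3 lower and 20 not called (4 and 3 adjusted over the list alone, camera adjusted p = 0.43). Pluripotency genes had 1 of 13 lower and 12 not called (1 adjusted over the list alone, camera adjusted p = 0.33), namely Dnmt3l, which fell by 2.53 ± 0.48.

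Without TTF replicate 2 the iHep counts against TTF were 789 higher and 785 lower, and without TTF replicate 3 they were 760 and 751. The iHep arrays formed 2 pairs, with rank correlations over features of 0.95 between replicates 1 and 2 and 0.978 between replicates 3 and 4 against 0.886 to 0.919 across the pairs. Each iHep array correlated more with the mixed-culture array (0.922 to 0.959) than with any TTF array. Among the TTF arrays, iHep replicates 1 and 2 correlated best with TTF replicate 1 (0.905 and 0.885). For iHep replicates 3 and 4 these were TTF replicates 2 and 3 (0.896 and 0.897 for replicate 3, 0.889 and 0.887 for replicate 4). Deviations from the group mean did not show these sets, with correlations of 0.02 and 0 between TTF replicate 1 and iHep replicates 1 and 2. Between TTF replicates 2 and 3 and iHep replicates 3 and 4 they lay between -0.05 and 0.04. With arrays put into the 2 sets of the rank correlations, 1096 of the 1309 higher and 1063 of the 1244 lower genes changed by at least 2-fold in both sets. This arrangement was chosen after seeing the data, and the genes had been selected on the same arrays. In a fit of the iHep and TTF arrays alone with the set as a block 1488 genes were higher and 1505 lower, against 1100 and 1125 in a fit of these arrays without the block. Of the genes called in the fit of all 3 groups, 1168 and 1146 were among them. Without iHep replicates 1 and 2, an alternative also chosen after seeing the data, 2016 were higher and 1995 lower, and camera no longer called the bile acid (adjusted p = 0.15), sterol (0.075), fatty acid oxidation (0.085) and interferon (0.25) lists. Without iHep replicates 3 and 4 the glucose (0.76), biliary (0.19), proliferation (0.94) and stomach, lung and pancreas (0.077) lists lost their calls. Among genes chosen after their values were seen, Xist, the X-inactivation RNA, lay at 2.02 and 1.95 on iHep replicates 3 and 4, at -8.84 and -7.1 on replicates 1 and 2, and at -8.39 or below on the TTF arrays. The Y-linked Eif2s3y lay at -9.04 and -8.58 on iHep replicates 3 and 4 and at 0.6 and 1.34 on replicates 1 and 2.

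**Figure D1:**
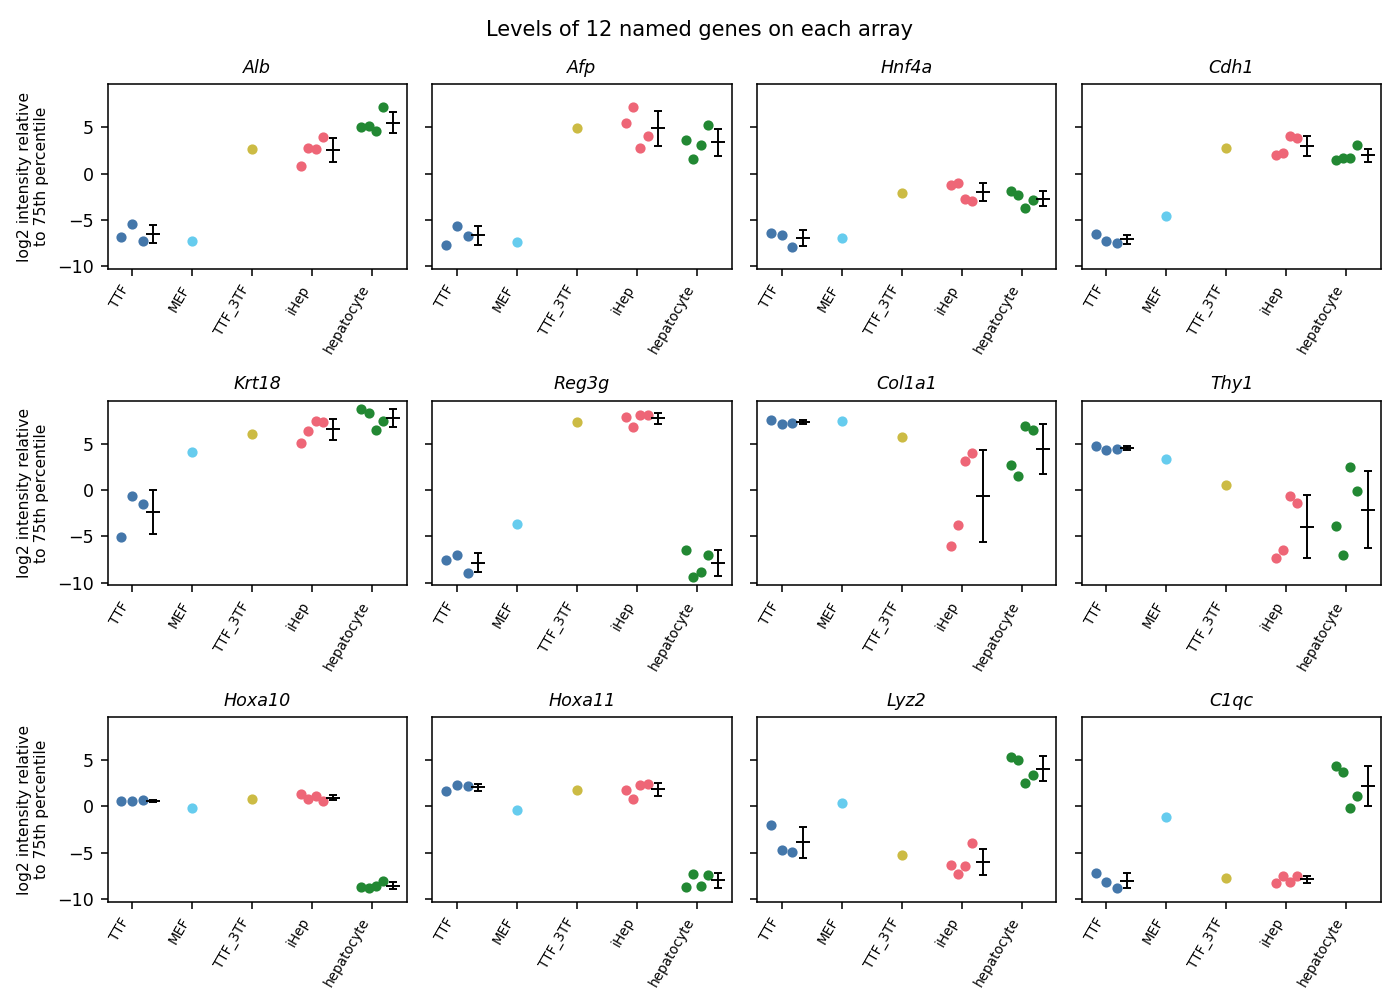
Levels of 12 named genes on each array, as log2 intensity relative to the array's 75th percentile, by group, with points for arrays and bars for the mean and SD of groups with replicates. Alb lay between 0.79 and 3.98 on the iHep arrays and between -7.26 and -5.4 on the TTF arrays, and Col1a1 separated iHep replicates 1 and 2 (-6.06 and -3.72) from replicates 3 and 4 (3.1 and 3.98).

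The comparison of cultured hepatocytes with TTF gives the reference difference between liver and fibroblast cultures. At the preset correlation the lists of liver secretory, epithelial, macrophage, endothelial and stellate genes were called higher in hepatocytes and the posterior Hox list lower. Only the last call was kept with an estimated correlation. Alb rose by 11.97 ± 0.79 (SE, n = 4 and 3, adjusted p = 1e-05), and Igfbp1, a liver-secreted binding protein of insulin-like growth factors, was among the largest increases at 13.8 ± 0.98 (adjusted p = 1.6e-05), with 2 and 1 of 3 TTF arrays above the limit. Foxa2 rose by 11.53 ± 0.34 (1 of 3 TTF arrays above the limit) and the bile acid receptor gene Nr1h4 by 7.84 ± 0.97. Hoxa11 fell by 10.01 ± 0.49 (adjusted p = 1.3e-06), and Crabp1, for a retinoic acid binding protein, fell by 10.85 ± 1.05, with 1 and 2 of 4 hepatocyte arrays above the limit. In all, 1426 genes were higher and 937 lower, and 60.3% of the calls were higher, against 34.1% with arrays scaled to equal medians and 49.3% after quantile normalization. Scaling to equal medians moved the median change of all genes from 0.069 to -0.328 here, from 0.07 to -0.087 for iHep against TTF and from -0.02 to 0.221 for iHep against hepatocytes.

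Plasma carrier proteins and apolipoproteins rose in 19 of 25 cases and 6 were not called (22 adjusted over the list alone, camera adjusted p = 5.5e-20, adjusted p = 0.061 with an estimated correlation). Coagulation and complement genes rose in 16 of 30 cases and 14 were not called (20 adjusted over the list alone, camera adjusted p = 1.5e-14, adjusted p = 0.11 with an estimated correlation), with Fgb up by 12.19 ± 0.68 and the lectin pathway gene Mbl2 at least 1738-fold higher. Liver transcription factors rose in 12 of 22 cases, 1 fell and 9 were not called (15 and 1 adjusted over the list alone, camera adjusted p = 1.3e-07, adjusted p = 0.11 with an estimated correlation). Cytochrome P450 and drug metabolism genes rose in 17 of 43 cases and 26 were not called (27 adjusted over the list alone, camera adjusted p = 5.8e-11, adjusted p = 0.11 with an estimated correlation), Cyp3a13 being at least 622-fold and Cyp4b1 at least 270-fold higher. In the urea cycle and amino acid list 6 of 26 rose and 20 were not called (10 adjusted over the list alone, camera adjusted p = 0.00038, adjusted p = 0.35 with an estimated correlation), with Arg1, for arginase, up by 6.76 ± 1.39 (levels from -2.65 to 4.78 on the hepatocyte arrays). Epithelial junction and keratin genes rose in 22 of 40 cases and 18 were not called (26 adjusted over the list alone, camera adjusted p = 8.7e-17, adjusted p = 0.074 with an estimated correlation), Krt8 by 12.82 ± 1.48 and Krt18 by 10.14 ± 1. Cyp3a11 (0.4 ± 0.62), Col1a1 (-2.92 ± 2.3) and Vim (-0.71 ± 0.47) were not called.

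Macrophage and leukocyte genes rose in 19 of 24 cases and 5 were not called (21 adjusted over the list alone, camera adjusted p = 1.2e-16, adjusted p = 0.14 with an estimated correlation). The complement gene C1qc rose by 10.25 ± 0.94 with 1 of 3 TTF arrays above the limit, and the protease gene Ctss by 9.95 ± 0.84 with 2 of 3. Endothelial genes rose in 17 of 22 cases and 5 were not called (19 adjusted over the list alone, camera adjusted p = 2e-11, adjusted p = 0.14 with an estimated correlation), Emcn being at least 169-fold higher. Hepatic stellate cell genes rose in 6 of 16 cases and 10 were not called (8 adjusted over the list alone, camera adjusted p = 0.00049, adjusted p = 0.14 with an estimated correlation), including Lrat, which esterifies retinol, at 6.72 ± 0.6 with 1 of 3 TTF arrays above the limit. The mean level of the leukocyte list was 1.33 and 0.68 on hepatocyte replicates 1 and 2 and -2.21 and -1.44 on replicates 3 and 4, all above the highest TTF array at -5.68. The matrix list lay at -1.1 and -1.8 on hepatocyte replicates 1 and 2 and at 1.17 and 0.97 on replicates 3 and 4. Matrix genes fell in 12 of 40 cases, 1 rose and 27 were not called (19 and 1 adjusted over the list alone, camera adjusted p = 8.7e-10, adjusted p = 0.28 with an estimated correlation), and Lum, for the proteoglycan lumican, was the one that rose (5.8 ± 1.07).

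Posterior Hox genes fell in 10 of 17 cases and 7 were not called (11 adjusted over the list alone, camera adjusted p = 1.4e-11), and this call was kept at adjusted p = 0.026 with an estimated correlation. Hoxa10 was at least 201-fold lower. Anterior Hox genes had 6 of 20 lower, 1 higher and 13 not called (7 and 3 adjusted over the list alone, camera adjusted p = 0.13, but 0.019 without hepatocyte replicate 3). Sterol and fatty acid synthesis genes fell in 9 of 24 cases and 15 were not called (14 adjusted over the list alone, camera adjusted p = 4.6e-07, adjusted p = 0.17 with an estimated correlation). Sqle, for squalene epoxidase, fell by 1.66 ± 0.37, a call that ended without TTF replicate 2 (adjusted p = 0.067) or 3 (0.075), and without hepatocyte replicates 1 and 2, an alternative chosen after seeing the data (0.093). The fetal liver list had 4 of 16 higher, 4 lower and 8 not called, as when adjusted over the list alone, with a median and mean above 0 and a test pointing down (camera adjusted p = 0.88). Biliary markers had 4 of 17 higher and 13 not called (6 adjusted over the list alone), with a median below 0, a mean above 0 and a test pointing up (camera adjusted p = 0.43). Cdkn2a fell by 4.1 ± 0.68. Without TTF replicate 2 the hepatocyte counts were 797 higher and 451 lower, without TTF replicate 3 they were 732 and 449, and without hepatocyte replicate 2 the lower count was 606. Without hepatocyte replicates 1 and 2, chosen after seeing the data, 797 were higher and 469 lower.

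The comparison of iHep with hepatocytes shows what still separated the induced cells from the reference cells. At the preset correlation the intestinal, sterol synthesis and posterior Hox lists were called higher in iHep and the macrophage, endothelial, stellate and plasma protein lists lower, through part of their members. Only the posterior Hox call was kept with an estimated correlation. Reg3g was higher by 15.62 ± 0.67 (SE, n = 4 and 4, adjusted p = 1.1e-06), with 1 of 4 hepatocyte arrays above the limit. Hoxa11 was higher by 9.8 ± 0.45 (1 of 4 hepatocyte arrays above the limit) and Hoxa10 at least 260-fold higher. Alb was lower in iHep, with a log2 fold change of -2.96 ± 0.74 (adjusted p = 0.023). That call ended under 3 alternatives chosen after seeing the data, without hepatocyte replicates 3 and 4 (adjusted p = 0.071), without hepatocyte replicates 1 and 2 (0.072) and without iHep replicates 1 and 2 (0.076). Igfbp1 fell by 10.82 ± 0.91. The macrophage-associated Wfdc17 fell by 13.73 ± 0.89, with 1 of 4 iHep arrays above the limit. Not called were Afp (1.52 ± 0.98), Hnf4a (0.7 ± 0.56), Foxa3 (-1.01 ± 0.63), Ttr (1.34 ± 1.17), Cdh1 (1.05 ± 0.54) and Krt18 (-1.19 ± 0.93). In all, 1192 genes were higher and 1432 lower in iHep, and 45.4% of the calls were higher, against 64.5% with equal medians.

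Posterior Hox genes were higher in 10 of 17 cases and 7 were not called (11 adjusted over the list alone, camera adjusted p = 8.7e-10), again kept at adjusted p = 0.026 with an estimated correlation. Their mean level lay between -3.93 and -3.1 on the iHep arrays, between -3.23 and -2.82 on the TTF arrays and between -7.48 and -7.04 on the hepatocyte arrays. Sterol and fatty acid synthesis genes were higher in 17 of 24 cases and 7 were not called (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.2e-11, adjusted p = 0.11 with an estimated correlation), among them Lss, for lanosterol synthase, at 2.88 ± 0.3. Intestinal genes were higher in 9 of 23 cases and 14 were not called (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 6e-05, adjusted p = 0.11 with an estimated correlation), with the mucin gene Muc13 up by 7.28 ± 0.76 (1 of 4 hepatocyte arrays above the limit). Cftr was higher by 6.42 ± 0.6 and the epithelial factor gene Ehf by 4.27 ± 0.36. Macrophage and leukocyte genes were lower in 17 of 24 cases, 1 was higher and 6 were not called (19 and 1 adjusted over the list alone, camera adjusted p = 2.4e-12, adjusted p = 0.22 with an estimated correlation), C1qc being at least 652-fold lower. Endothelial genes were lower in 13 of 22 cases, 1 was higher and 8 were not called (15 and 1 adjusted over the list alone, camera adjusted p = 2.3e-07, adjusted p = 0.24 with an estimated correlation), with Emcn at least 132-fold lower. Stellate genes were lower in 6 of 16 cases and 10 were not called (8 adjusted over the list alone, camera adjusted p = 6.2e-05, adjusted p = 0.12 with an estimated correlation). Lrat fell by 6.56 ± 0.56, with 1 of 4 iHep arrays above the limit.

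Interferon response genes were lower in 9 of 23 cases and 14 were not called (14 lower adjusted over the list alone, camera adjusted p = 3.3e-06, adjusted p = 0.25 with an estimated correlation), Ifit1 by a log2 fold change of -3.37 ± 0.4. The list's mean level was -0.24 and -0.61 on hepatocyte replicates 1 and 2 and -1.9 and -2.37 on replicates 3 and 4. Plasma carrier proteins and apolipoproteins had 7 of 25 lower, 1 higher and 17 not called (10 and 1 adjusted over the list alone, camera adjusted p = 0.0022, adjusted p = 0.38 with an estimated correlation). Ambp, the precursor of alpha-1-microglobulin and bikunin, fell by 7.53 ± 0.72. Coagulation and complement genes had 9 of 30 lower, 2 higher and 19 not called (12 and 3 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.38 with an estimated correlation), with the clotting factor gene F10 at least 36.6-fold lower and C9 higher by 3.06 ± 0.61. Liver transcription factors had 6 of 22 lower, 1 higher and 15 not called (6 and 1 adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.29 with an estimated correlation), and Foxa1 fell by 4.6 ± 0.41 with 2 of 4 iHep arrays above the limit. The plasma list lost its call without iHep replicates 3 and 4 (adjusted p = 0.11) and the transcription factor list without hepatocyte replicates 1 and 2 (0.052), both alternatives chosen after seeing the data. Matrix genes were lower in 11 of 40 cases, 1 was higher and 28 were not called (14 and 1 adjusted over the list alone, camera adjusted p = 1e-05, adjusted p = 0.4 with an estimated correlation). This last call ended without hepatocyte replicates 3 and 4 (adjusted p = 0.24), likewise chosen after seeing the data. Junction and keratin genes had 6 of 40 higher, 1 lower and 33 not called (7 and 1 adjusted over the list alone, camera adjusted p = 0.032, adjusted p = 0.54 with an estimated correlation). That call ended with equal medians (adjusted p = 0.095), without iHep replicate 3 (0.053) or 4 (0.092) and without hepatocyte replicate 3 (0.25) or 4 (0.084). Of the alternatives chosen after seeing the data, it ended without both iHep replicates 3 and 4 (0.32), and its direction turned at 0.93 without both hepatocyte replicates 3 and 4. Without hepatocyte replicates 1 and 2, 774 genes were higher in iHep, and without iHep replicates 1 and 2 the counts were 1922 higher and 2218 lower.

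**Figure D2:**
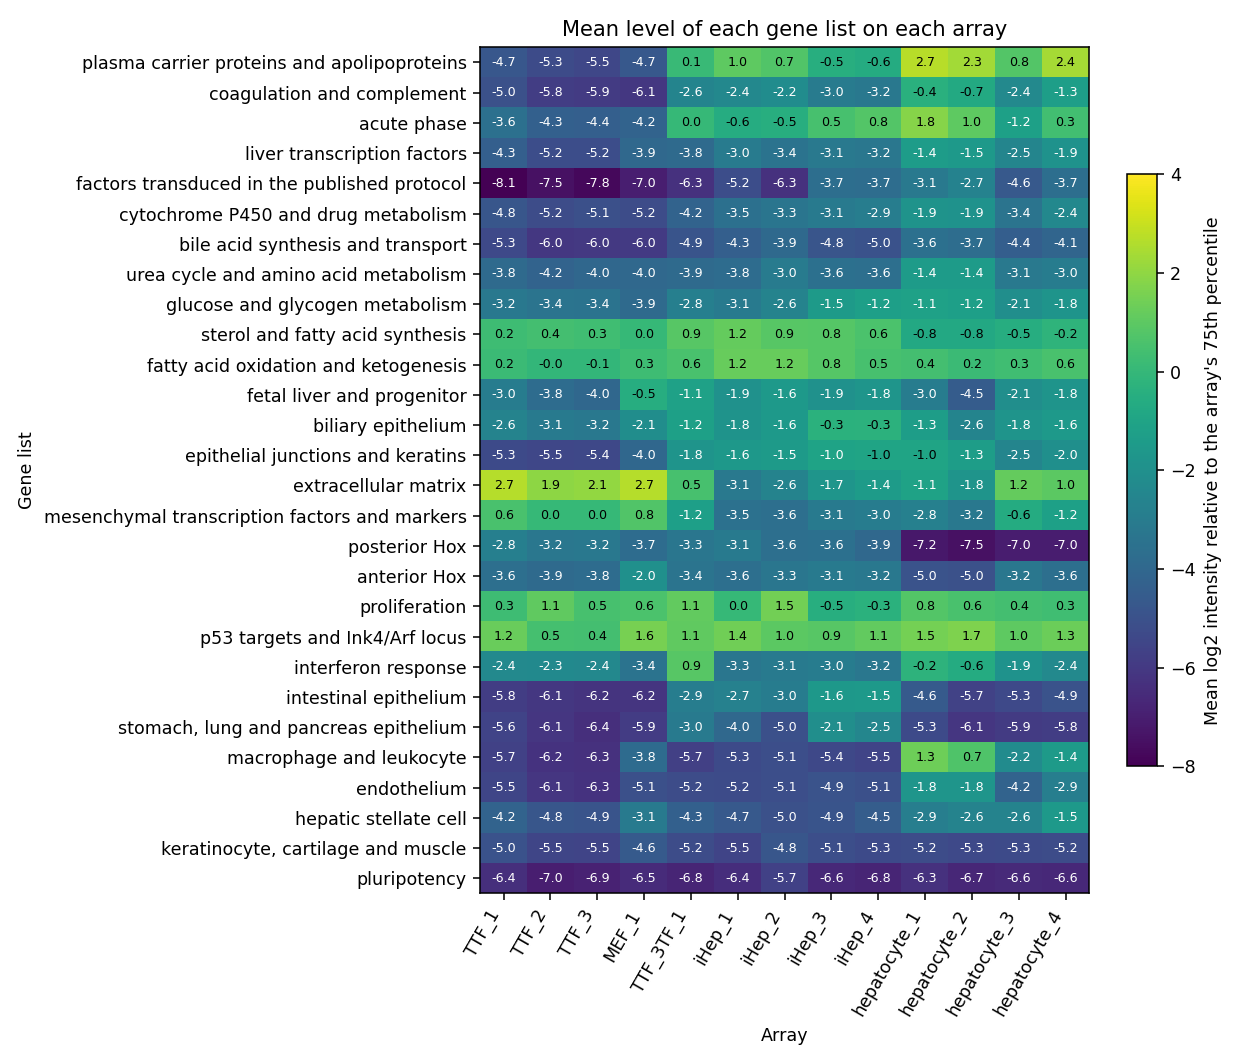
Mean level of each of the 28 gene lists (vertical axis) on each of the 13 arrays (horizontal axis), as log2 intensity relative to the array's 75th percentile, printed in each cell and shown by colour. The posterior Hox list lay at -7.04 or below on the hepatocyte arrays and at -3.93 or above on the iHep arrays, and the leukocyte list lay highest on hepatocyte replicates 1 and 2 (1.33 and 0.68).

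The design also asks how far the iHep arrays lie from fibroblast towards hepatocyte. On a line over all genes from the TTF mean (0) to the hepatocyte mean (1), the iHep arrays lay at 0.659 ± 0.021 (SD, n = 4). With each array left out of its own group mean, TTF lay at 0.072 ± 0.121 (SD, n = 3) and hepatocytes at 0.93 ± 0.194 (SD, n = 4), of which replicates 3 and 4 stood at 0.701 and 0.84. The mixed culture lay at 0.53 and MEF at 0.265. TTF replicate 1 alone stood at 0.211, near MEF, and TTF replicates 2 and 3 at 0.011 and -0.007. The spread of the shared TTF arrays alone gives a position of 0.08, and with the expected spread taken out the iHep position was 0.673. The iHep arrays also lay 1.51 to 1.66 log2 units off this line (root mean square over genes). The line includes the leukocyte, endothelial and stellate genes that were higher on the hepatocyte arrays, so a position is not a share of hepatocyte genes alone.

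**Figure D3:**
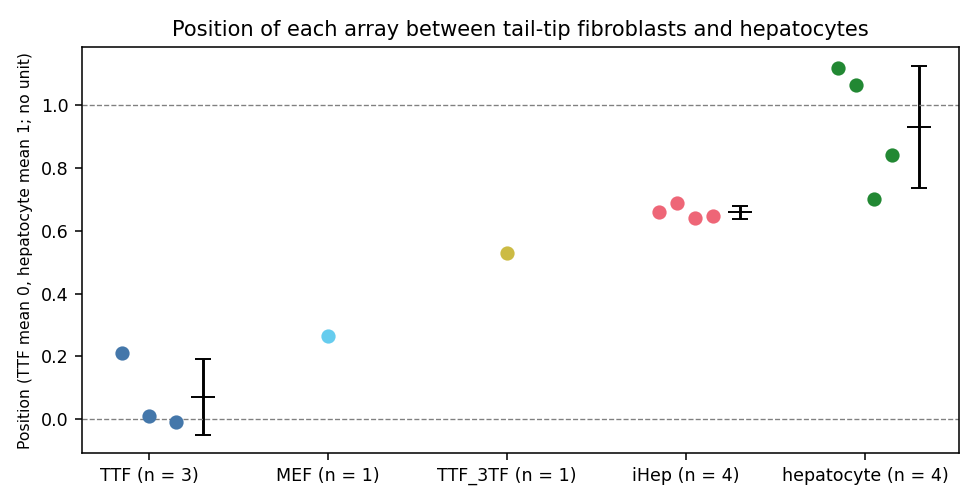
Position of each array (points) on the line from the TTF mean (0) to the hepatocyte mean (1), without unit, by group, with bars for the mean and SD of groups with replicates. The 4 iHep arrays sit between 0.642 and 0.688, the mixed culture at 0.53 and the MEF array at 0.265.

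Of the 1426 genes higher in hepatocytes than in TTF, 505 (35.4%) were also higher in iHep, 14 were lower and 907 were not called. Of these 907, 528 were called between iHep and hepatocytes. The 1426 include 19 of 24 leukocyte, 17 of 22 endothelial and 6 of 16 stellate genes, against 3, 4 and 2 higher in iHep than TTF. The 35.4% is therefore not a share of hepatocyte genes alone. Of the 937 genes lower in hepatocytes, 437 (46.6%) were also lower in iHep, 8 were higher and 492 were not called, 235 of them with a call between iHep and hepatocytes. Independent lists of these sizes would share 97.8 higher and 61.1 lower genes, against the 942 observed in all. In 100 simulations of unchanged groups every array was drawn anew with independent noise, and both comparisons used the same simulated TTF arrays. On average 0 genes were shared there. Those simulations hold no effect, so few genes can be called in them, and they do not gauge the sharing expected among called genes. The fold changes of both comparisons correlated across genes, which are not independent replicates, at r = 0.618 against 0.571 in the simulations, with a covariance of 1.614 against 0.198. The difference of the covariances was 1.416. It does not estimate a shared liver effect alone, since day and medium also set iHep and hepatocytes apart from TTF. The simulations also took the TTF arrays as independent, although TTF replicates 2 and 3 had a rank correlation of 0.984. The same sign in 69.2% of genes did not exceed the simulated 69.4%. The 3 TTF arrays are too few to split, so part of the excess over independent lists may come from the shared controls. The shared count was 539 without TTF replicate 2, 517 without TTF replicate 3 and 621 without hepatocyte replicates 1 and 2, the last chosen after seeing the data.

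**Figure D4:**
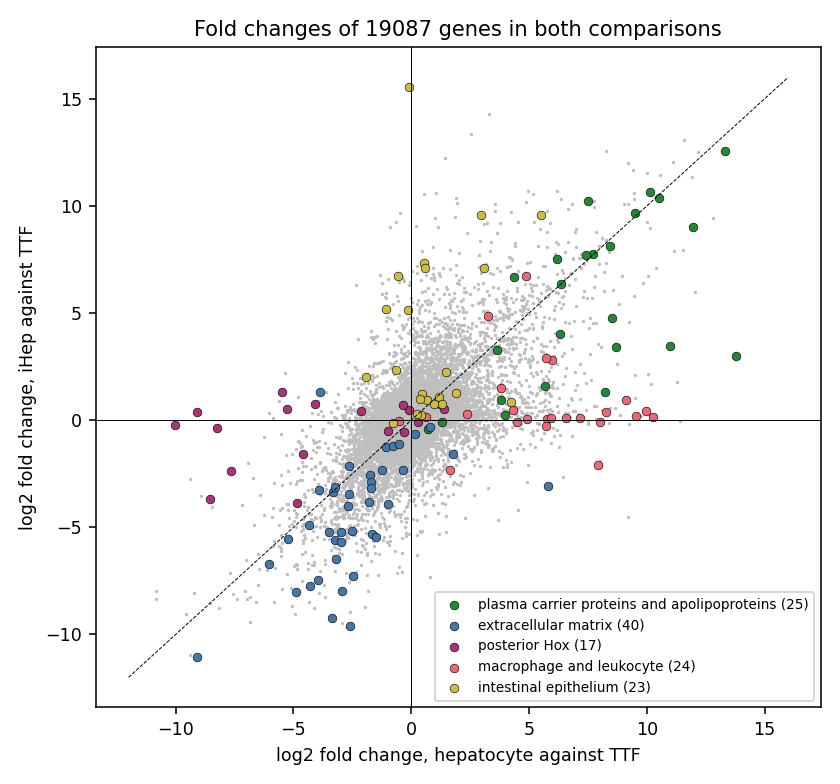
Log2 fold changes of 19087 genes against TTF, hepatocyte on the horizontal and iHep on the vertical axis, with each point a gene, 5 gene lists in colour and a dashed line of equal change. Hoxa11, of the posterior Hox list, has a change of -10.01 on the hepatocyte axis, and C1qc, of the leukocyte list, one of 10.25.

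The mixed culture, described by the labels as holding both fibroblasts and epithelial cells, was set against the 3 TTF arrays without a test, counting genes at least 4-fold away from the TTF mean and outside the TTF range. By this count 1239 genes were higher and 700 lower. Reg3g was higher by 15.14 on the log2 scale, Ahsg was at least 19519-fold higher and Fgb was higher by 13.17. Alb (9.16), Afp (11.55), Cdh1 (9.83) and Hnf4a (4.83) were also counted higher. Col1a1 (-1.55) and Vim (-1.43) were not counted. Plasma carrier proteins were higher in 18 of 25 cases and junction genes in 25 of 40, while 16 of 40 matrix genes were lower. Interferon response genes were higher in 18 of 23 cases, with a median at percentile 100 among 10000 random lists matched on mean level. Proliferation genes also reached percentile 100, with 0 of 39 counted, so that rank alone does not set a list apart. The random lists take genes as independent. Among the lowest genes were Marchf9, at least 374-fold lower, and Alkal1, at least 56.5-fold lower. Abcb6, a mitochondrial transporter gene, was also among them, with a log2 difference of -7.11. These falls rest on 1 array and exceed that of matrix genes, whose median stood at 31.1% of the TTF level. Whether they would hold on another array was not tested.

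The MEF array, a p19Arf-null fibroblast of another origin, had 767 genes higher and 389 lower than TTF by the same count. Upk3b, a mesothelial and urothelial gene, was at least 1392-fold higher, the mesothelial and kidney factor gene Wt1 was higher by 10.76 and the fetal growth factor gene Igf2 by 10.16. Eif2s3y was at least 1116-fold lower and the cartilage matrix gene Cilp at least 863-fold lower. Alb (-0.74), Afp (-0.66) and Hnf4a (0.05) were not counted, whereas Foxa2 was higher by 10.54, Krt18 by 6.54 and Gata4 by 2.49. The TTF means of Wt1 (-8.77) and Foxa2 (-8.8) were near the floor, so the size of their differences depends on low values. The Foxa2 level of 1.74 on this array lay above the iHep arrays (-1.32 to -0.43), so a higher level than in TTF was not a feature of iHep and hepatocytes alone. Fetal liver and progenitor genes were higher in 8 of 16 cases, anterior Hox genes in 8 of 20 and macrophage genes in 11 of 24. Each list had a median at percentile 100, as did the p53 target list with 1 of 18 counted higher. Posterior Hox genes were higher in 4 and lower in 6 of 17 cases.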

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

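No test in this part was chosen only after its result was seen. Features without a gene name lie outside the gene comparisons, yet many passed the same limma threshold. Of 11309 such features, 476 were called between iHep and TTF (220 higher, 256 lower), 518 between hepatocytes and TTF (283 higher, 235 lower) and 602 between iHep and hepatocytes (325 higher, 277 lower). Which transcripts they detect was not analysed here.

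Across array positions, list means and the genes named here, 240 groups of 4 arrays were searched for an array standing far from the others of its group. Chance would flag about 1 in 20 groups (12 expected) if arrays were independent, which the correlated pairs of arrays speak against. The search found 9, all for single genes. In iHep these were replicate 2 for Ehf (-0.18, others -0.73 to -0.69) and Foxa3 (-5.32, others -3.33 to -3.15) and replicate 1 for Sftpd (-0.44, others 2.86 to 3.23). On hepatocyte replicate 4 Cdh1 lay at 3.04 (others 1.47 to 1.69), Lss at -1.02 (others -1.81 to -1.74) and Nr1h4 at 2.57 (others 1.2 to 1.4). On hepatocyte replicate 3 Dnmt3l lay at -1.28 (others -2.14 to -2.01) and Myo1a at -6.04 (others -5.11 to -5.06), and on replicate 1 Vim lay at 1.77 (others 0.84 to 0.86).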

How the results depend on the processing

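Leaving out pairs of arrays, the common floor and the block of array sets were chosen after seeing the data, and all other settings before the data were examined. Of 253 named gene results 225 were called, 146 of them under all settings and 0 reversed. Of 81 list results 51 were called, and 33 were kept under all settings other than the estimated correlation, which kept 2. Each list under the fits of only the compared groups, the trend and robust option and the common floor kept its call.

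Against 937 lower in hepatocytes than TTF and 1192 higher in iHep than hepatocytes, equal medians gave 1923 and 1832, and the cause was not tested. Without hepatocyte arrays 1 and 2, counts were 797 higher and 469 lower in hepatocytes than TTF, 774 higher in iHep than hepatocytes and 621 shared, and without iHep arrays 1 and 2 they were 2016 higher and 1995 lower than TTF and 1922 higher and 2218 lower than hepatocytes (the cause was not tested). The iHep position was 0.698 with the lowest 25% of genes left out, 0.631 over called genes and 0.533 without hepatocyte arrays 3 and 4, where the hepatocyte mean itself moves by construction. Testing each probe on its own turned the fetal liver list of hepatocytes against TTF up (adjusted p = 0.0061), and leaving out hepatocyte arrays 3 and 4 turned the junction list of iHep against hepatocytes down (adjusted p = 0.93). The cause was not tested for either.

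Leaving out 1 replicate gave 760 to 1412 genes higher and 751 to 1338 lower in iHep than TTF, 732 to 1517 and 449 to 1024 in hepatocytes than TTF, and 855 to 1300 and 984 to 1596 in iHep than hepatocytes. The position ranged from 0.62 to 0.687 and the shared count from 517 to 1023. The lowest counts against TTF came without TTF replicate 3, which leaves 2 TTF arrays. The number left is not the whole reason, since leaving out TTF replicate 1 also leaves 2. Without replicate 1, counts were 1152 higher and 1002 lower in iHep than TTF, and 1411 and 730 in hepatocytes than TTF. For the single arrays the ranges were 1175 to 1431 higher and 739 to 800 lower in the mixed culture, and 720 to 981 higher and 389 to 516 lower in MEF.

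Whether replicate numbers pair the samples was not settled by deviations from the group mean, which correlated over 0.1 in 4 of 10 same-number pairs (range -0.09 to 0.18). Deviations of iHep replicates 1 and 2 correlated with those of hepatocyte replicates 1 and 2 at 0.07 to 0.13. For replicates 3 and 4 of both groups this was 0.11 to 0.15. Between replicates 1 and 2 of 1 group and 3 and 4 of the other it was -0.15 to -0.07, and the cause was not tested. With the replicate block, counts were 1135 higher and 1039 lower in iHep than TTF, 1437 and 852 in hepatocytes than TTF, 1126 and 1407 in iHep than hepatocytes, 892 shared and 50 lists called. Signal over background limits low genes, as between 63.2% and 83% of features were measured per array, and folds are bounds only where no array of the dimmer group lay above the limit.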

Other observations

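Tests of the set of genes higher in iHep than in both other groups, of loss of the Y chromosome and MEF cells, of left-over fibroblasts and scaling, and of the hepatocyte arrays were chosen after the result was seen. Relative to both TTF and hepatocytes, 514 genes were higher and 488 lower in iHep, by calls in both comparisons. The intestinal list had 8 of its 23 measured genes among the 514 against 0.62 expected. They were Cdx2, a master factor of intestinal identity, Vil1, Lgals4, Muc13, Myo1a, the glucose transporter gene Slc5a1, Reg3g and Agr2, of which those outside the naming rule were chosen after their values were seen. The cytochrome P450 list had 7 of 43 (1.16 expected), the junction list 6 of 40 (1.08) and the stomach, lung and pancreas list 3 of 23 (0.62). Among the 488 lower genes the matrix list had 9 of 40 (1.02) and the mesenchymal list 9 of 37 (0.95). A one-sided Fisher's exact test over 56 tests gave adjusted p of 5e-06 for the intestinal, 0.0019 for the P450, 0.0073 for the junction and 0.14 for the stomach, lung and pancreas list. For the matrix and mesenchymal lists it gave 1.1e-05 and 8e-06. These values decide nothing, since the set was made from the calls already seen in both comparisons and the test takes genes as independent. With an estimated correlation camera did not call the intestinal list in either comparison (adjusted p = 0.061 against TTF and 0.11 against hepatocytes). The calls of the single intestinal genes stand, while a wider programme of other endoderm epithelia stays open.

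On the mixed-culture array 77 genes lay above and 8 below all TTF and iHep arrays by at least 4-fold, and 11 of the 77 belonged to the 23 interferon response genes. The list's mean level was 0.9 there, against -2.39 to -2.32 on the TTF arrays and -3.29 to -2.98 on the iHep arrays. With 1 array, no explanation was tested.

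Xist lay at 1.08 or above on iHep replicates 3 and 4 and the MEF array and at -7.1 or below on the other 10 arrays, while the Y-linked Eif2s3y, Kdm5d and Uty were above the limit on those 10 arrays alone (genes chosen after their values were seen). Loss of the Y chromosome from male cells is argued against by Xist, which lay 10.34 log2 units above the highest TTF array. For cells from the MEF culture, Hox genes put these arrays at 0.31 and 0.26 from TTF (0) to MEF (1). On that line iHep replicates 1 and 2 lay at 0.08 and 0.15 and the hepatocyte arrays between 0.48 and 0.74. The Hox values argue against the MEF culture only if iHep cells keep the Hox pattern of their source, which was not tested independently. Female origin cannot be told apart from other sources by Usp9y (highest level -7.22), which was above the limit on only 2 of 13 arrays, nor another X chromosome by X-linked escape genes, whose lower value lay -0.08 relative to the highest of TTF and iHep replicates 1 and 2. The labels give no sex. The cells on the TTF arrays as source of iHep replicates 3 and 4 are argued against by Xist (2.02 and 1.95, TTF at -8.39 or below). Eif2s3y (-9.04 and -8.58, TTF at 2.32 or above) and Kdm5d (-8.22 and -8.53, TTF at -0.64 or above) argue against it too. Together, the high Xist level and Eif2s3y, Kdm5d and Uty under the limit argue against male cells on iHep replicates 3 and 4. Cells from an animal of another sex than those of the TTF arrays may underlie the pattern. Usp9y and the escape genes could not decide this. The hepatocyte arrays lay with TTF (Xist at -7.38 or below, Eif2s3y at 2.35 or above). The difference in these genes therefore enters the comparison of iHep with hepatocytes too.

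Posterior Hox genes in iHep stood at 79.8% to 114% of the TTF level (median over genes), but at 2.81% to 4.1% in hepatocytes. Fibroblasts left in the colonies are argued against by matrix genes, at most 7.17% of the TTF level on an iHep array. Scaling and low values are argued against too, as the camera adjusted p for iHep against hepatocytes stayed at or below 4.3e-08 under quantile normalization, equal medians, the low filter and the common floor. Over both Hox lists each iHep array lay within 1.76 log2 units (root mean square) of the TTF mean, against at least 2.58 from MEF and 3.64 from the hepatocyte mean. The medians hide 2 of 17 posterior Hox genes called lower in iHep than TTF. Hoxc13 lay at -6.80 in iHep against -2.92 in TTF, and Hoxc12 at -3.75 against -0.05. A tail-tip Hox pattern may therefore have been kept in part through induction, a hypothesis from the same data. For iHep replicates 3 and 4 the cells on the TTF arrays are argued against as source, so closeness to the TTF mean cannot show that their source pattern was kept.

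Leukocyte, endothelial and stellate lists lay above every TTF array on all hepatocyte arrays, the smallest gap being 1.27 log2 units, which is consistent with other liver cells in the hepatocyte cultures. Hepatocyte replicates 3 and 4 had matrix genes at 34.3% and 36.3% of the TTF level against 7.26% and 5.11% on replicates 1 and 2. Tail-tip fibroblast RNA is argued against by posterior Hox genes, at least 3.67 log2 units below the level it predicts. A lower share of hepatocytes as the whole cause is argued against by the leukocyte list, which moved the other way (-2.12 log2 units between the higher of replicates 3 and 4 and the lower of replicates 1 and 2). Some liver lists lay lower on replicates 3 and 4 too, such as coagulation (-2.36 and -1.27 against -0.36 and -0.7) and urea cycle (-3.13 and -2.95 against -1.42 and -1.43). The plasma carrier list was lower on replicate 3 (0.8) but not on replicate 4 (2.4), against 2.73 and 2.32. Alb was highest on replicate 4 (7.14, with 4.59 on replicate 3 and 5.07 and 5.17 on replicates 1 and 2). A lower share together with more of other mesenchymal liver cells stays open, and the cultures' preparation was not analysed here.

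With each array taken as a unit, chance in the grouping can be excluded for the gene counts, since only 1 of the 35 splits, the real one, reached each count. This holds only if arrays are independent, which the correlated pairs speak against (rank correlation 0.984 for TTF replicates 2 and 3, 0.978 for iHep 3 and 4, and 0.98 and 0.974 for hepatocytes 1 and 2 and 3 and 4). With such pairs as units, the splits are too few for a share under 0.05. The real counts were 2553 for iHep against TTF (highest other 439), 2363 for hepatocytes against TTF (701) and 2624 for iHep against hepatocytes (447). For the number of lists called it can be excluded under the same condition for iHep against TTF, with 17 against 14 in the highest other split, but not for hepatocytes against TTF, where 9 of the 35 splits called at least 17 and the highest other called 19. Nor can it be excluded for iHep against hepatocytes, where 3 of the 35 splits did and the highest other called 18.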
